A study of Mus musculus with 4 samples.

How the data were processed

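Single-cell RNA libraries of the 4 groups (PKA hyperplasia, WT hyperplasia, PKA tumor and WT tumor, with 1 library each) were analysed from the processed files. Groups were taken from the sample titles. Per the labels' protocols, glands were digested with collagenase and hyaluronidase and then with trypsin and dispase, whereas tumors were minced and digested with collagenase and hyaluronidase alone. Cells were then sorted by FACS and loaded for the 10x Chromium 3' kit with a target of 5000 cells per library and 50000 reads per cell. Per the series design, glands and tumors of the same mouse were processed, although the mice of each stage were killed at different ages.

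The deposited count files hold raw UMI counts per gene and barcode. The submitters' processing notes name Cell Ranger, STAR 2.5.3a and featureCounts from Subread 1.6.0 with GRCm38/mm10, and the annotation release is not given in the sources used here. The authors' per-cell tables give counts of UMIs and genes, which equalled the sums of the count files, the fraction of mitochondrial UMIs as deposited by the authors, and a cell class. Per the series design the classes were assigned with Monocle2 from marker genes. The count files held 5179, 4858, 5800 and 2934 barcodes for WT hyperplasia, PKA hyperplasia, WT tumor and PKA tumor, and the authors gave 3808, 3818, 5181 and 2638 cells in their annotation. The filter between them is not stated; barcodes without an annotation were left out of all comparisons. Counts were given for 31781 genes in any file and 20479 in all 4 files, and a gene without a UMI in a library counted as 0. Other per-cell columns of the tables were not used.

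UMIs were summed over the annotated cells of a library, since cells are not replicates, and scaled by the library total to CPM. With 1 library per group, no test was made and no p-value is given. Log2 ratios of CPM carry exact 95% intervals from the conditional binomial distribution, and shares of cells carry exact Clopper-Pearson 95% intervals. A share of 0 allows 3 cells of the total. Before the data were examined, the comparisons, 25 gene lists, cell type markers and the rule for named genes were fixed. Named genes were the 12 highest and 12 lowest log2 ratios of (CPM + 10) per comparison among genes of at least 100 CPM in the higher library, leaving out mitochondrial, ribosomal protein, haemoglobin and predicted genes, Xist, Tsix, the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and markers of non-epithelial cells. Members of the gene lists, the markers named in the series design and PKA pathway genes could be named as well. For each list, members with at least 10 UMIs in both libraries together counted as measured. Their median log2 ratio, with 0.5 UMIs added, was placed among 10000 random lists of the same size drawn from the same 20 expression bins. Ratios were also taken within each class of at least 50 cells in both libraries.

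Cells of all 4 libraries were clustered together from 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1. Doublets were scored with Scrublet in each library, which called 45 of 15445 cells (0.291%); so low a share was taken to mean that the caller had not worked, although doublets removed before deposit, of which the labels say nothing, would also give few calls. No doublets were removed here. For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. Gene positions were taken from the GRCm38 annotation of the reference. Work was done with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3.

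The steps were tested on simulated counts, drawn with counting error alone from the mean over both libraries of each comparison, with 200 genes changed. Differences between mice, class shares or dissociation were not simulated, so the values below hold for counting error only. A gene counted as recovered when its whole interval lay on the true side of 0. At a fold of 2, 80% of changed genes were recovered in PKA against WT hyperplasia (16671 genes), 82% in PKA against WT tumor (20146 genes), 90% in WT tumor against hyperplasia (19402 genes) and 76% in PKA tumor against hyperplasia (18755 genes). Intervals covered 96.2%, 95.9%, 96.0% and 96.1% of unchanged genes in the same order. Of 200 unchanged lists, 6%, 8.5%, 3.5% and 4% fell outside the central 95% of random lists.

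Alternatives fixed before the data were examined were TMM factors, totals without mitochondrial, ribosomal protein and milk genes, the mean of each cell's CPM, an unweighted mean over classes, all barcodes, cells with at least 500 genes and at most 10% mitochondrial counts, called doublets left out, other minimums of UMIs or CPM, another added CPM, clusters named by markers at resolutions 0.5, 1 and 2, and other thinning. Added after the data were seen were leaving out cells above the 95th percentile of doublet scores of their library (133, 150, 259 and 125 cells, since tied scores at the limit were kept) and leaving out cells with 3 or more UMIs of stromal or leukocyte markers, with and without Dcn among them. Leaving out the cluster with most of the Klk6 UMIs of WT tumor was also added then, for the epidermal genes only. The calculation with the same class shares in both libraries was not among the alternatives fixed beforehand. Areg and Adipoq are not analysed here.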

Results

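Gene expression was measured in single cells from mammary tissue of MMTV-PyMT mice, in which polyoma middle T antigen is expressed in the mammary epithelium and hyperplastic glands progress to tumors. The 4 groups, with 1 library each, were hyperplastic glands and tumors of mice with activated protein kinase A (PKA), the cAMP-dependent kinase, and of mice labelled WT. How PKA was activated is not stated in the labels. Glands came from mice of 8 to 9 weeks, and tumor age was 16 to 20 weeks in the sample labels and 22 weeks in the series design. The annotated cells numbered 3808 in WT hyperplasia, 3818 in PKA hyperplasia, 5181 in WT tumor and 2638 in PKA tumor. They held 10797950, 10648097, 24499374 and 16758734 UMIs in that order, with medians of 2637.5, 2557, 4391 and 5890.5 UMIs per cell. No difference had a replicate check, so every interval given is a 95% interval of counting error only and compares these libraries rather than the conditions.

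The classes of epithelial cells were compared to ask which cells made up the glands and tumors. Luminal Progenitor 1 cells, named by the authors from Cd14, Kit and Lalba, were the most frequent class in each library. They made up 71.5% (70.0 to 72.9) of WT hyperplasia cells and 75.6% (74.2 to 76.9) of PKA hyperplasia cells. In the tumors they made up 45.2% (43.9 to 46.6) of WT cells and 81.8% (80.2 to 83.2) of PKA cells. Mature Luminal cells, which carry the hormone receptor genes Pgr, Esr1 and Prlr, made up 3.05% (2.52 to 3.64) of WT and 6.57% (5.81 to 7.41) of PKA hyperplasia cells. The order was the other way in tumors, with 16.8% (15.8 to 17.9) of WT cells and 6.71% (5.78 to 7.73) of PKA cells. Basal cells, marked by Krt14, Krt5 and Snai2, made up 5.25% (4.57 to 6.01) of WT and 5.97% (5.24 to 6.77) of PKA hyperplasia cells. No tumor cell carried the Basal name, which allows shares of up to 0.0579% in WT and 0.114% in PKA tumor. Luminal Progenitor 2 cells were named in hyperplasia only, at 20.2% (19.0 to 21.5) in WT and 11.9% (10.9 to 13.0) in PKA.

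Classes named in tumors only were Lumino-Basal, defined by Krt14, Krt8 and Cd14, and EMT-like, defined by Trim29, Vim, Cldn6 and Sox4. The authors' names gave 1198 Lumino-Basal cells in WT tumor, or 23.1% (22.0 to 24.3), and 66 in PKA tumor, with a share between 1.94 and 3.17%. EMT-like cells numbered 768 in WT tumor, or 14.8% (13.9 to 15.8), and 238 in PKA tumor, or 9.02% (7.96 to 10.2). Among their 10 leading genes, the Lumino-Basal and EMT-like classes held none of their own markers in either tumor. The Luminal Progenitor 1 class of WT tumor held none of its own either. In PKA tumor, the Lumino-Basal class held the basal marker Krt17, and the EMT-like class the luminal progenitor marker Lalba. The cells were therefore also compared by numbered clusters of all 4 libraries together. Cluster 7 held 1028 of the 1198 WT and 52 of the 66 PKA Lumino-Basal cells, and 1057 WT tumor cells and 70 PKA tumor cells in all. Cluster 10 held 366 of the 768 WT and 201 of the 238 PKA EMT-like cells, but also 71 WT and 445 PKA tumor cells of Luminal Progenitor 1. A further 338 WT EMT-like cells lay in cluster 9. Luminal Progenitor 1 cells of the tumors fell mostly into cluster 9 (1128 cells) and cluster 14 (862 cells) in WT and into cluster 8 (1573 cells) in PKA, and a cluster mostly from 1 library may be that library rather than a cell type. The sort before library preparation is not described in the labels and can set any of these shares.

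**Figure D1:**
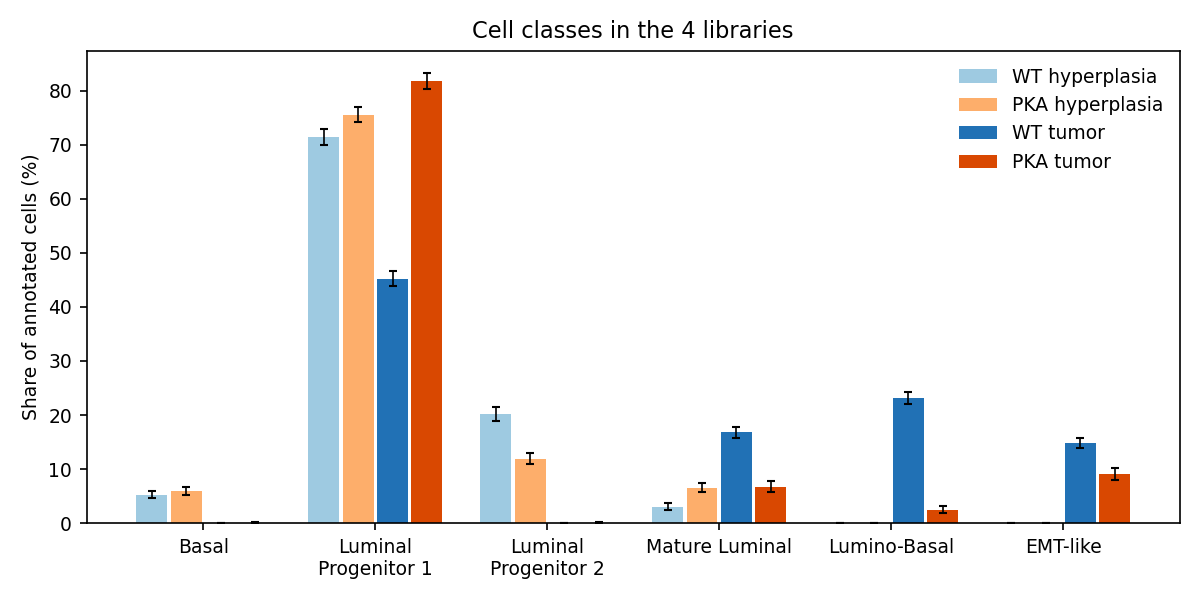
Share of annotated cells (percent) in each class named by the authors, with bars for the 4 libraries and exact 95% binomial intervals that cover counting error only. Lumino-Basal cells stood at 23.1% (1198 cells) in WT tumor against 66 of 2638 cells in PKA tumor, and Luminal Progenitor 1 cells at 45.2% and 81.8%.

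PKA and WT hyperplasia were compared to ask what activated PKA goes with before tumors form. Genes of the PKA pathway itself lay close together: Prkaca, the catalytic subunit, was at 35.0 CPM in PKA and 29.1 CPM in WT (log2 ratio 0.27, 0.05 to 0.49), and Prkar1a, a regulatory subunit, at 235 and 258 CPM (-0.13, -0.21 to -0.05). Gnas, whose locus holds overlapping transcripts so that its count is uncertain, had 53 and 49 UMIs (0.13, -0.45 to 0.72). Fam25c was 17.4-fold higher in PKA (4.12, 3.84 to 4.42), and the growth factor Ptn 5.19-fold higher (2.38, 2.23 to 2.52). Calca, which encodes calcitonin and CGRP, was 119-fold lower in PKA (-6.89, -7.55 to -6.30), at 23 UMIs against 2768. The caseins Csn1s1 and Csn2 were 13.6-fold (-3.76, -3.89 to -3.63) and 11.2-fold (-3.48, -3.64 to -3.33) lower. The ribosomal protein pseudogene Rps3a3 was high in the WT library alone, and whether reads were counted alike in both hyperplasia libraries is not known.

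The same comparison was made for gene lists, by the median log2 ratio of the members and its percentile among random lists matched on expression. Mature luminal genes were higher in the PKA library, with a median of 0.55 at percentile 100 and 9 of 11 members above 0 beyond counting error. Among them were Cited1 (1.75, 1.59 to 1.92), a transcriptional co-regulator, and the surface antigen gene Ly6d (0.97, 0.93 to 1.01). With the same class shares in both libraries, the median of the mature luminal list was 0.12. Basal genes had a median of 0.46 at percentile 100, with 12 of 16 higher, among them the smooth muscle genes Acta2 (0.94, 0.86 to 1.02) and Cnn1 (1.04, 0.81 to 1.27). Within the Basal class, Krt14 stood at 4226 CPM in PKA and 2972 CPM in WT. Krt5 stood there at 532 and 465 CPM, and Snai2 at 181 and 182 CPM. Basal cells also held more UMIs in PKA, with medians of 1975.5 and 1731.5 per cell, so their larger part of the RNA can raise this list. Interferon response genes had a median of 0.43 at percentile 100, with 12 of 14 higher, as for Isg15 (0.79, 0.73 to 0.85) and Irf7 (0.64, 0.58 to 0.69). Luminal progenitor genes had a smaller median of 0.19 at percentile 99.7, with Ltf (1.40, 1.34 to 1.47) and Cxcl1 (1.34, 1.28 to 1.39) the highest. S phase genes were lower in PKA, with a median of -0.50 at percentile 0 and 8 of 16 lower beyond counting error, such as the helicase subunit Mcm3 (-1.39, -2.05 to -0.77). Antigen presentation genes had a median of -0.40 at percentile 0, with 11 of 15 lower, from B2m (-0.60, -0.62 to -0.58) to the class II genes H2-Aa (-1.46, -1.89 to -1.05) and Cd74 (-1.15, -1.37 to -0.94). Cd74 was at 500 CPM in the WT Basal class, which also carried the fibroblast gene Dcn at 741 CPM and the macrophage gene C1qa at 137 CPM. Milk protein genes (median -0.14, percentile 1.74, with a slightly higher sum), nuclear oxidative phosphorylation genes (-0.18, 0.26) and the ribosomal protein list (-0.11, 0.01, with -0.07 for the coding genes of the tumor comparison) also lay lower in PKA. The 4 EMT-like genes had a median of -0.48 at percentile 0.77, which turned to 0.11 when members needed 100 UMIs. The medians of CREB target genes (0.04, 77.3) and PKA pathway genes (0.07, 81.6) did not stand apart from random lists. Of 18 CREB target genes, 5 were higher and 6 lower beyond counting error, and of 18 PKA pathway genes, 4 were higher and 4 lower.

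Mature Luminal cells carried most of the RNA of several of these genes, and their share was higher in the PKA library. Within that class, Fam25c was at 2286 CPM in PKA and 224 CPM in WT, Ptn at 2896 and 1075 CPM, and Calca at 28.9 and 7047 CPM. Interferon response genes were higher with PKA within Luminal Progenitor 1 (median 0.45) and Luminal Progenitor 2 cells (0.44), whereas the medians were -0.20 in Mature Luminal and -0.04 in Basal cells. With every class weighted equally, the Basal list had a median of 0.24 and AW112010, among the 12 highest genes with PKA, turned to -0.26, whereas with the same class shares in both libraries it stood at 0.83, or 0.553 of its log2 ratio over all cells.

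**Figure D2:**
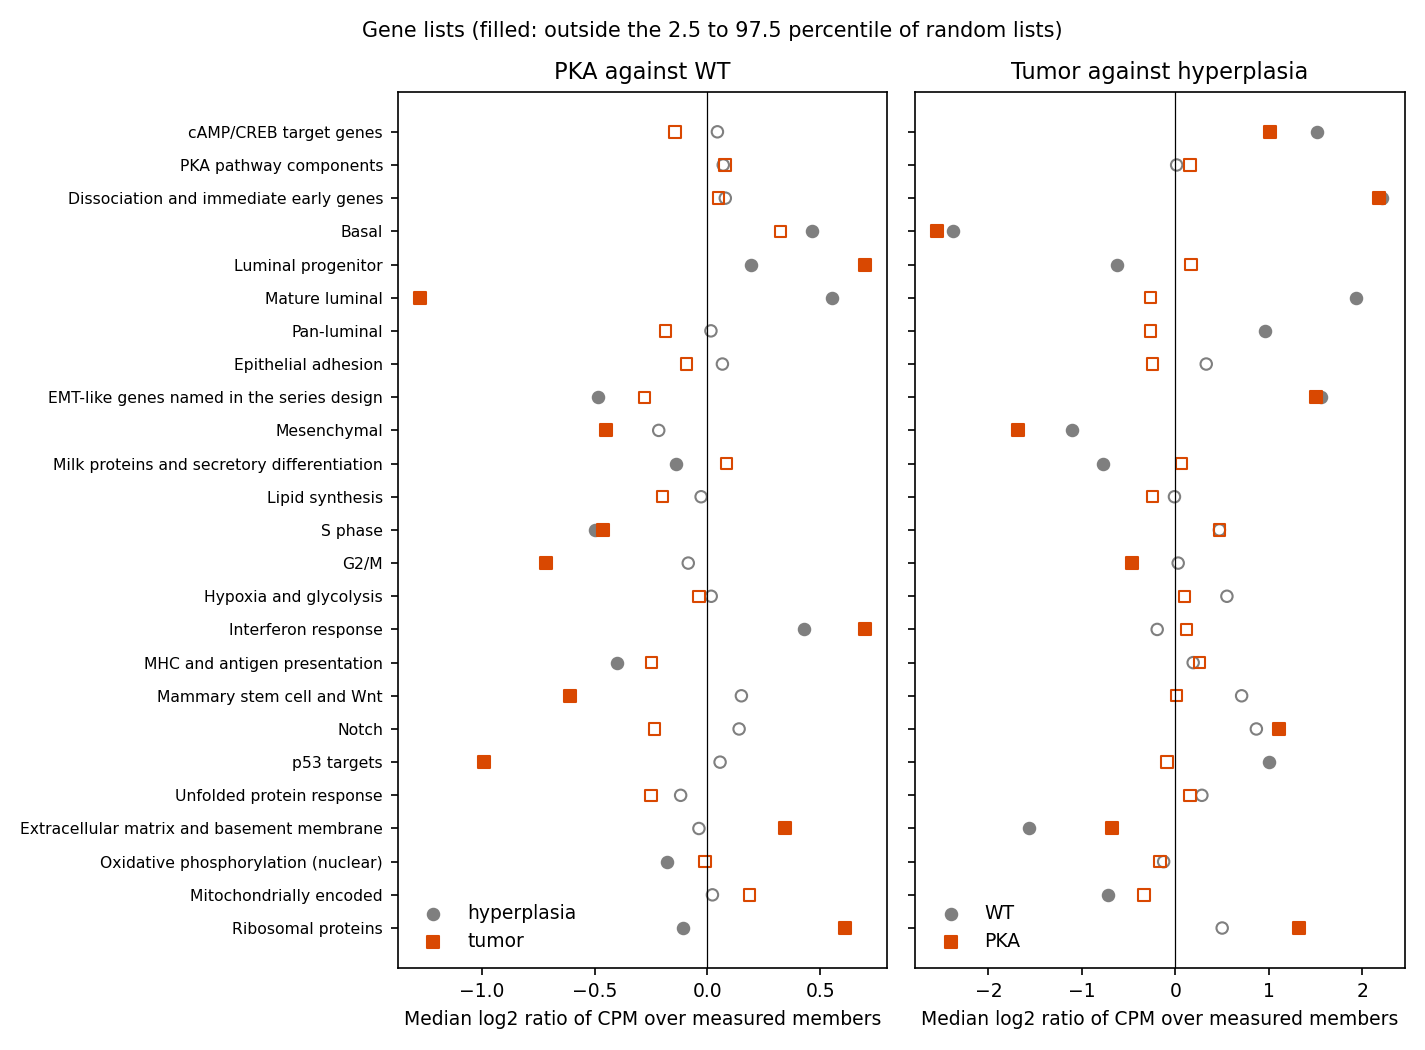
Median log2 ratio of CPM over the measured members of each fixed gene list, for PKA against WT (left) and tumor against hyperplasia (right), with filled symbols for lists outside the central 95% of random lists. Mature luminal genes stood at 0.55 in hyperplasia and -1.27 in tumor for PKA against WT, and interferon response genes at 0.43 and 0.70.

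PKA and WT tumors were compared to ask how tumors with activated PKA differed. The acute phase genes Saa2 and Saa1 were 19.3-fold (4.27, 4.19 to 4.34) and 11.4-fold (3.51, 3.47 to 3.55) higher in the PKA tumor, although reads of these close paralogs can be shared. Npy, which encodes neuropeptide Y, was 11.3-fold higher (3.50, 3.40 to 3.60), and Lalba, which encodes the milk protein alpha-lactalbumin, 5.21-fold higher, at 3373 against 647 CPM (2.38, 2.36 to 2.41). Klk6, a kallikrein protease, was 83.6-fold lower in the PKA tumor, at 4.65 against 389 CPM (-6.38, -6.73 to -6.06). The epidermal genes Asprv1 (-3.66, -3.77 to -3.55), Krt79 (-4.76, -5.08 to -4.46) and Klk10 (-5.03, -5.44 to -4.64) were lower as well. These 4 genes were mostly found in cluster 11, with 134 WT and 2 PKA tumor cells, which held 96.1% of the WT tumor UMIs of Klk6, 83.5% of those of Asprv1, 77.0% for Krt79 and 93.5% for Klk10. Without that cluster, a step added after the values were seen, the log2 ratios were -4.33 (-5.25 to -3.54), -1.16 (-1.28 to -1.03), -2.97 (-3.34 to -2.62) and -1.28 (-1.77 to -0.82) in that order. Upk3a, an uroplakin gene, was 22.0-fold lower (-4.46, -4.64 to -4.29), and Gpx3, a mature luminal marker, 9.14-fold lower (-3.19, -3.30 to -3.08). Among pathway genes, Prkaca was at 76.8 and 74.6 CPM (0.04, -0.06 to 0.15), Prkar1a at 273 and 390 CPM (-0.52, -0.57 to -0.46), and the PKA inhibitor gene Pkia at 12.2 and 3.96 CPM (1.62, 1.26 to 1.98).

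Among the lists, luminal progenitor genes had a median of 0.70 at percentile 100, with 11 of 12 higher in the PKA tumor, including Kit (1.15, 1.06 to 1.23) and Cd14 (0.77, 0.74 to 0.80). Mature luminal genes had a median of -1.27 at percentile 0, with 9 of 10 lower, including Pgr (-2.04, -2.32 to -1.78) and Foxa1 (-1.33, -1.46 to -1.20). Mature Luminal cells were fewer in the PKA tumor, and with the same class shares in both libraries the median was -0.48, with Pgr at -0.90 and Foxa1 at -0.15. Prom1 (0.56), Prlr (0.54) and Esr1 (0.18) then stood above 0, and the other measured members below. Interferon response genes had a median of 0.70 at percentile 100, with 13 of 14 higher, including Ifi27l2a (1.97, 1.87 to 2.07) and Rsad2 (1.52, 1.41 to 1.64). All 10 p53 target genes were lower in the PKA tumor, with a median of -0.99 at percentile 0, including Cdkn1a (-1.37, -1.42 to -1.31) and Bax (-1.05, -1.11 to -0.99). S phase genes (median -0.46, percentile 0.13) and G2/M genes (-0.72, 0) were lower, the latter with 10 of 16 lower beyond counting error, including Birc5 (-1.13, -1.42 to -0.85). Stem cell and Wnt genes had a median of -0.61 at percentile 0, which turned to 0.10 when members needed 100 UMIs, and went both ways, with the Wnt target Axin2 lower (-3.91, -4.76 to -3.16) and Lgr6 higher (0.64, 0.52 to 0.76). Matrix and basement membrane genes had a median of 0.35 at percentile 97.6, with Col4a1 (1.74, 1.38 to 2.11) and Tnc (2.70, 2.06 to 3.39) higher and Fn1 lower (-2.00, -2.44 to -1.59). Mesenchymal genes had a median of -0.45 at percentile 0.72 on low counts, with Vim (1.18, 0.99 to 1.38) and Col3a1 (-5.00, -6.89 to -3.62) going opposite ways, and the median turned to 0.25 with every class weighted equally. The ribosomal protein list had a median of 0.61 at percentile 100, but only 85 of its 340 measured members matched annotated coding genes, with a median of 0.33. Basal genes had a median of 0.32 at percentile 96.0 but a lower sum, 853 against 1455 CPM, with Krt14 (-0.92, -0.97 to -0.86), Lgals7 (-0.47, -0.51 to -0.43) and Cxcl14 (-3.77, -4.03 to -3.53) lower, and antigen presentation genes a median of -0.25 but a higher sum, 12609 against 8254 CPM, with B2m higher (1.14, 1.12 to 1.15). The medians of CREB target genes (-0.14, 34.7) and PKA pathway genes (0.08, 88.7) did not stand apart. Members went both ways beyond counting error, with 8 of 19 CREB target genes higher and 10 lower. Of 18 PKA pathway genes, 7 were higher and 3 lower.

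Within Luminal Progenitor 1 cells alone, the medians kept their sign for interferon response (0.55), p53 target (-0.85), mature luminal (-0.82), luminal progenitor (0.43) and G2/M genes (-1.10). Several mature luminal genes stood low in these cells. In WT tumor, Gpx3 was at 11.5 CPM there and 11.9 CPM in EMT-like cells, against 1923 CPM in Mature Luminal cells, and Pgr was at 2.67 CPM. Stray RNA from Mature Luminal cells, which were a larger share of WT tumor, can therefore set the mature luminal value. The p53 target genes had a median of 0.09 within Mature Luminal cells. G2/M genes had a median of -2.94 in Mature Luminal cells, but the mean of the class medians, with every class weighted equally, was 0.33. Lumino-Basal cells (66 in PKA tumor), EMT-like cells (238) or both therefore had a G2/M median above 0. These genes were rare, with 78.7 CPM summed over the list in PKA tumor and 127 CPM in WT tumor. In classes of few cells the 0.5 UMIs added to each sum can move such medians, the -2.94 of Mature Luminal cells included. Fibroblast markers summed to 223 CPM in WT tumor and 26.0 CPM in PKA tumor, and the WT sum was mostly Dcn, which stood at 900 CPM in WT Mature Luminal cells where Col1a2 had no UMI.

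**Figure D3:**
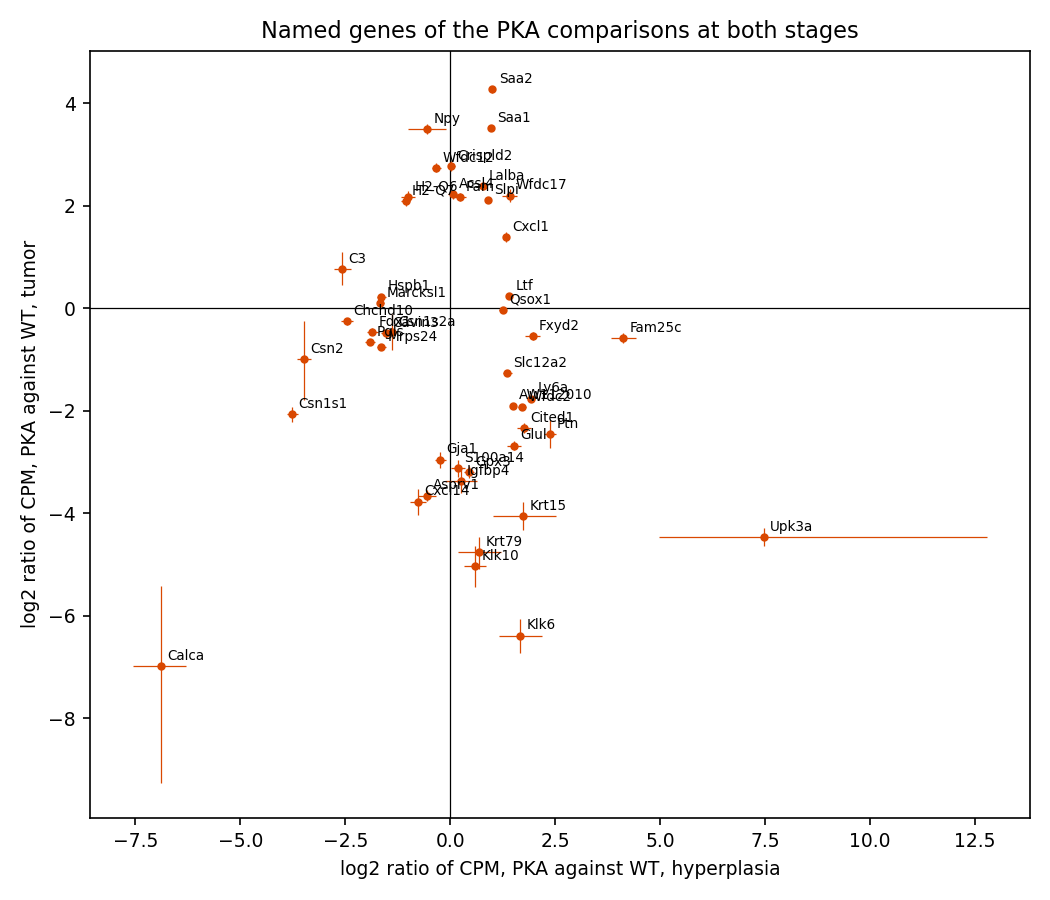
Log2 ratio of CPM, PKA against WT, in hyperplasia (horizontal) and in tumor (vertical) for the genes named in either comparison, with 95% intervals of counting error. Calca lay low at both stages, whereas Glul, Cited1, Wfdc2 and Ly6a lay above 0 in hyperplasia and below 0 in tumor.

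The differences between the PKA and WT libraries were set side by side at both stages, and the change between stages was not tested. Over all cells, interferon response genes were higher with PKA at both stages, and S phase genes lower. Within Luminal Progenitor 2 cells of hyperplasia, however, the S phase median lay above 0. G2/M genes stood at -0.08 (percentile 18.2) in hyperplasia, with the intervals of 10 of 16 members holding 0, and at -0.72 (percentile 0) in tumor. Mature luminal genes changed sides, from 0.55 in hyperplasia to -1.27 in tumor, a difference of -1.83, and so did the share of Mature Luminal cells; with the same class shares in both libraries the medians were 0.12 and -0.48. Cited1, for example, was at 38.2 CPM in WT and 129 CPM in PKA hyperplasia, and at 316 CPM in WT and 62.7 CPM in PKA tumor. The p53 target genes were at 0.06 in hyperplasia and -0.99 in tumor. Lalba was higher with PKA at both stages (0.77, 0.74 to 0.80 in hyperplasia), and so were Saa1 (0.96, 0.94 to 0.98) and Saa2 (1.01, 0.97 to 1.04).

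Tumors were compared with hyperplasia within each genotype to ask how the epithelium differed between the stages. Immediate early genes stood higher in tumors, with list medians of 2.22 in WT and 2.18 in PKA, both at percentile 100. Klf2, a transcription factor gene, was at 1056 CPM in WT tumor against 3.24 CPM in WT hyperplasia (8.35, 7.87 to 8.87), and at 1108 against 3.29 CPM in PKA (8.40, 7.92 to 8.92). Fos was 27.5-fold higher in WT (4.78, 4.73 to 4.84) and 27.6-fold higher in PKA (4.79, 4.74 to 4.84), and the Notch target Hes1 46.4-fold (5.54, 5.40 to 5.68) and 24.0-fold (4.58, 4.44 to 4.73). Basal genes stood lower in tumors, with medians of -2.38 in WT and -2.55 in PKA, both at percentile 0, and Acta2 was 31.3-fold lower in PKA (-4.97, -5.19 to -4.75). Pfn1, which encodes the actin-binding protein profilin, was counted 50.4-fold lower in WT (-5.66, -5.75 to -5.56) and 54.7-fold lower in PKA (-5.77, -5.89 to -5.66). Each library listed its own genes, 5341 of them in tumor files only and 1526 in hyperplasia files only, and whether reads were counted alike at both stages is not known.

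Other lists differed between the genotypes in the stage comparison, a difference that was likewise not tested. Mature luminal genes had a median of 1.93 at percentile 100 in WT and -0.26 at percentile 14.9 in PKA, and p53 target genes stood at percentile 99.4 in WT, with 9 of 10 higher in tumor, and at percentile 28.1 in PKA, with a median of -0.09. Pan-luminal genes stood at 0.96 (percentile 99.8) and -0.27 (33.1), luminal progenitor genes at -0.62 and 0.17, and milk protein genes at -0.77 (0.04) and 0.06 (65.3). Matrix genes were lower in tumors of both genotypes, at -1.57 (0) and -0.68 (0.08), and so were mesenchymal genes, at -1.11 (0) and -1.68 (0). CREB target genes stood at 1.51 (100) and 1.01 (100), and this list holds immediate early genes such as Fosb (4.87, 4.76 to 4.99 in WT) and Dusp1. The 4 EMT-like genes stood at percentiles 98.9 and 98.1, with Sox4 20.7-fold higher in PKA (4.37, 4.23 to 4.52). The coagulation genes Fgb (9.01, 8.03 to 10.22) and Fgg (6.51, 5.96 to 7.11) were higher in WT tumor. The cytokine genes Il24 (-9.30, -10.14 to -8.58) and Csf3 (-5.09, -5.21 to -4.97) were lower in WT tumor. They were lower in PKA tumor as well, at -6.99 (-7.48 to -6.54) and -5.51 (-5.66 to -5.36). Glands and tumors were digested with different enzymes for different times, so stage and dissociation cannot be told apart here. All stage ratios are relative to library totals, and TMM scaling shifted them by -0.20 in WT and -0.19 in PKA. With only the classes present at both stages, weighted equally, the Basal medians turned to 0.02 in WT and 0.29 in PKA.

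Cells with UMIs of both Krt14, a basal keratin, and Krt8, a luminal keratin, were counted after thinning each cell to 2000 UMIs. They made up 7.51% (6.54 to 8.56) of 2718 WT hyperplasia cells, 9.93% (8.82 to 11.1) of 2670 PKA hyperplasia cells, 13.5% (12.5 to 14.5) of 4753 WT tumor cells and 11.7% (10.4 to 13.0) of 2451 PKA tumor cells. Without thinning the shares were 9.38%, 12.6%, 20.5% and 19.9%. Within the Lumino-Basal class the share was 27.8% (25.2 to 30.5) in WT and 46.0% (33.4 to 59.1) in PKA, and within Luminal Progenitor 1 cells of the tumors 13.1% (11.7 to 14.6) and 12.4% (10.9 to 13.9). Mature Luminal cells, which should lack Krt14, gave a background of 2.96% in WT tumor and 3.49% in PKA tumor, at median depths of 5559 and 8414.5 UMIs. Thinning left out 1090, 1148, 428 and 187 cells below 2000 UMIs in the 4 libraries. Cells with Krt5 and Krt8 made up 0.0421% (0.00510 to 0.152) of WT tumor cells and 0.0408% (0.00103 to 0.227) of PKA tumor cells. Cells with Vim and Krt8 made up 1.83% (1.47 to 2.25) and 3.35% (2.67 to 4.14), against 0.118% and 0.581% in Mature Luminal cells.

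**Figure D4:**
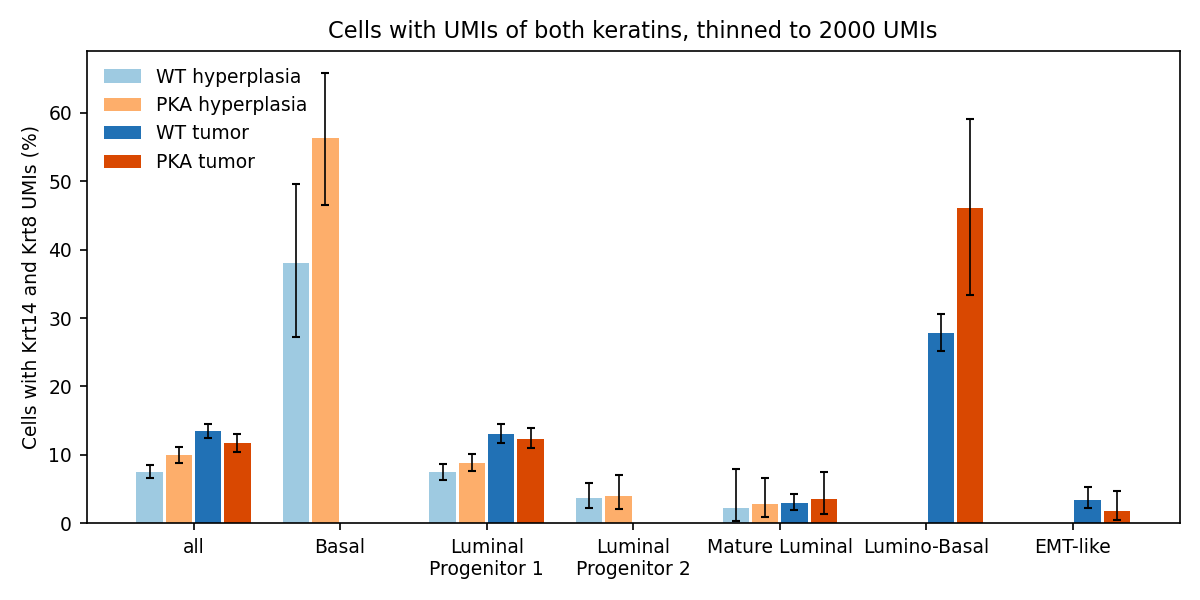
Share of cells (percent) with UMIs of both Krt14 and Krt8 after thinning to 2000 UMIs per cell, in all cells and by class, with bars for the 4 libraries and exact 95% binomial intervals of counting error. Lumino-Basal cells stood at 27.8% in WT tumor and 46.0% in PKA tumor, and all cells at 13.5% and 11.7%.

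The genes named for the largest differences lie on several chromosomes of GRCm38. Calca (ENSMUSG00000030669.13) spans 114631478 to 114636357 on chromosome 7, which also holds Klk6 (ENSMUSG00000050063.18) at 43824499 to 43832030, Saa1 (ENSMUSG00000074115.5) at 46740497 to 46742980 and Saa2 (ENSMUSG00000057465.5) at 46751790 to 46754313. Csn1s1 (ENSMUSG00000070702.9) at 87666208 to 87682578 and Csn2 (ENSMUSG00000063157.9) at 87692624 to 87699630 lie on chromosome 5. Fam25c (ENSMUSG00000043681.5) spans 34351881 to 34355433 on chromosome 14, Lalba (ENSMUSG00000022991.5) 98480400 to 98482721 on chromosome 15, and Npy (ENSMUSG00000029819.6) 49822710 to 49829507 on chromosome 6. Klf2 (ENSMUSG00000055148.7) spans 72319033 to 72321656 on chromosome 8, Pfn1 (ENSMUSG00000018293.4) 70651850 to 70654644 on chromosome 11, and Cited1 (ENSMUSG00000051159.16) 102247381 to 102252181 on chromosome X.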

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

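The tests on doublets, on naming as the whole cause and on transcript length were chosen after the result was seen, as was the gene set of the test on class shares, and how the transcript length and shared read tests were read was changed after their values were seen; no difference between stages or genotypes below was tested.

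Lumino-Basal cells made up 23.1% of WT tumor cells and 66 of 2638 PKA tumor cells, and doublets of a basal and a luminal cell could carry both keratins. The Krt14 level of the class in WT tumor would need 15.9% of its RNA from Basal cells like those of hyperplasia. The upper bounds of 14 other basal genes were at a median of 0.0755 of the level this implies, with Acta2 at 14.2 CPM against 694 implied and Snai2 without a UMI. This argues against such doublets for the class as a whole, although 4 genes such as Krt17 and Lgals7 stood above that level. Krt14 differed within the class, at 537 CPM in its cells of cluster 7 and 6591 CPM in cluster 11, so the implied levels are a mean over unlike cells. Doublets of other pairs were left open by the class's median UMIs, at 1.28 times those of Luminal Progenitor 1 cells, between the bounds of 1.2 and 1.5, and by an earlier count of 3 genes in cluster 7 over 2 times above every other cluster, which was then replaced. A mix of cells carries the genes of each part at the weight of that part. On that ground the other 8 clusters of the WT tumor could together give at most 26.9% of the RNA of the class's 1028 cells in cluster 7. For its 134 cells in cluster 11 the part was 0.394. These values lay under a bound of 0.5, but that bound was set after they were seen, so the test cannot decide. Doublets of other pairs stayed open.

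Classes may also have been named in each library separately: outside the class, 10.8% of 2388 PKA and 9.13% of 3648 WT tumor cells carried Krt14 and Krt8 after thinning, against 27.8% within it in WT, which could make up 41.4% (1.57 to 80.2) of the 21.2% of PKA cells outside the class that would have to join it to reach the WT share. Clusters 7 and 11 were made from all libraries together without the names, and held 23.0% (21.8 to 24.2) of WT and 2.73% (2.14 to 3.42) of PKA tumor cells, with only 19 of the latter outside the class, and at 3 resolutions the upper bound for PKA was at most 0.158 of the lower bound for WT. However, clusters of these tumors did split by library. Cluster 9 held 1479 WT and 59 PKA tumor cells and cluster 14 held 919 and 57, although both were mostly Luminal Progenitor 1 cells. A low PKA share in clusters 7 and 11 could arise in the same way, so it cannot argue against naming. The keratin count alone, with an upper bound of 80.2%, fell short of the whole gap. Naming, a true difference between the tumors, doublets of other pairs or a mix of these stayed open.

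Mature luminal genes had a median of 0.55 with PKA in hyperplasia and -1.27 in tumor, a difference of -1.83, and this might come from the share of Mature Luminal cells. With equal class shares in both libraries, the median over the list was 0.12 in hyperplasia (11 genes) and -0.48 in tumor (10 genes). The median part of the log2 ratio that remained was 0.112 (quartiles -0.407 to 0.666) in hyperplasia, under the bound of 0.25 for class shares as the cause, and 0.430 (quartiles 0.0578 to 0.583) in tumor, above it and below the bound of 0.5 against them. An earlier form of the test added 5 genes chosen because they changed sides, which gave 0.499 and 0.419 and was dropped. How much belongs to the number of such cells and how much to their expression stayed open.

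The ribosomal protein list had a median of 0.61 with PKA in tumor and -0.11 in hyperplasia, a difference of 0.72, but 255 of its 340 members in tumor, such as pseudogenes, did not match annotated coding genes (median 0.66), and the 85 coding genes stood at 0.33 and -0.07, with 60 of them higher in the PKA tumor (summed CPM 45565 against 43135). Reads shared with pseudogenes could raise them, and genes without a shared stretch stood at -0.12 (20 genes) against 0.43 (47 genes) for those sharing most, a ratio of -0.282 that met the bound set beforehand for shared reads as the cause. However, 17 of those 20 genes had transcripts of 800 bases or more, where genes without sharing stood at -0.13, 5 genes sharing up to 50% at 0.41 and 11 sharing more at -0.11, so the test was then read as open. Short transcripts could also be captured differently, and coding genes under 800 bases stood at 0.73 (52 genes) against -0.11 (33 genes) for longer ones, whereas other genes of matched length and expression stood at -0.09 (-0.18 to 0.11), or -0.259 of the median of the coding genes. The matched genes also went with length, at 0.19 for the coding genes under 800 bases and -0.26 for the longer ones. The length test was read as open after its interval had been replaced by the interval of that median, and shared reads, length and a true difference all remained.

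The log2 ratio of Cited1 for PKA against WT differed by -4.09 between tumor and hyperplasia. For Glul the difference was -4.20, and for Ly6a -3.69. Wfdc2 had a difference of -3.65. AW112010 differed by -3.39. Slc12a2 had -2.62. In the other direction, H2-Q7 differed by 3.15, and Apoc1 by 2.32. Among these 8 genes, 6 were highest in the Mature Luminal class by at least 2 times, all but H2-Q7 and Apoc1. With the same class shares in both libraries, the values for hyperplasia and tumor lay closer together for Cited1 (0.80 and -1.14), Glul (0.89 and -1.51) and Ly6a (1.49 and -0.52). H2-Q7 (-1.05 and 2.06) and Apoc1 (-1.03 and 1.32) changed little.

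Among the 296 PKA tumor barcodes without an annotation, Hbb-bs stood at 6355 CPM against 1.97 CPM in annotated cells, with UMIs in 5 barcodes. Hba-a1 stood at 1873 against 9.91 CPM, with UMIs in 3 barcodes. Hba-a2 stood at 1555 against 0.119 CPM, and Hbb-bt at 1330 CPM against no UMI in annotated cells, each in 2 barcodes.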

How the results depend on the processing

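Of the alternatives counted below, only the filters on stromal or leukocyte UMIs and on doublet scores were chosen after the data were seen. Leaving out the cluster with most of the Klk6 UMIs of WT tumor was also chosen after the values were seen. The calculation with the same class shares in both libraries was not among the alternatives fixed beforehand. Neither of these steps is in the counts below. The 4 groups had 1 library each, stage went with dissociation and age, and the sort gate and the filter on cells are not described. Counting each result once per setting, 89 class shares stayed within their interval and 9 moved, 1161 list medians stayed, 31 moved and 8 reversed, and 769 named genes stayed, 190 moved and 1 reversed. Named genes chosen again by another minimum or another added CPM were mostly the same in all 8 choices. With TMM factors, 97 list medians stayed and 3 moved, and 70 named genes stayed and 26 moved. With an unweighted mean over classes, 77 list medians stayed, 19 moved and 4 reversed, whereas only 13 named genes stayed, 82 moved and 1 reversed.

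Leaving out cells with stromal or leukocyte UMIs gave, for the Basal share, WT hyperplasia at 4.51%, for the Mature Luminal share, WT hyperplasia at 2.51% and WT tumor at 13.2%, a Luminal Progenitor 1 share of 47.2% in WT tumor, and a Mesenchymal median of 0.33 for PKA against WT in tumor, or 0.59 without Dcn in the filter. Dcn in Mature Luminal cells makes this filter remove them by construction. Col1a1, Col1a2 and Col3a1 are markers of the filter with or without Dcn and also members of the Mesenchymal list. The filter therefore removes UMIs of these members by construction as well. Cells with at least 500 genes and at most 10% mitochondrial counts gave Luminal Progenitor 1 shares of 73.6% in WT and 77.2% in PKA hyperplasia and Luminal Progenitor 2 shares of 18.3% and 10.7%, and clusters named by markers at resolution 2 gave a Basal share of 4.54% in WT hyperplasia; the causes were not tested. The unweighted mean over classes gave a Basal median of 0.24 and AW112010 at -0.26 (0.83 with the same class shares in both libraries) for PKA against WT in hyperplasia, a Mesenchymal median of 0.25 and a G2/M median of 0.33 for PKA against WT in tumor, and Basal medians of 0.0193 in WT and 0.29 in PKA for tumor against hyperplasia. By construction it gives each shared class the same weight and leaves out the Basal class between stages. With members of at least 100 UMIs, the EMT-like list had a median of 0.11 in hyperplasia and the stem cell and Wnt list 0.10 in tumor for PKA against WT, and the cause was not tested. Cells with Krt14 and Krt8 made up 4.71%, 6.80%, 8.67% and 7.43% of WT hyperplasia, PKA hyperplasia, WT tumor and PKA tumor cells when thinned to 1000 UMIs, and 9.38%, 12.6%, 20.5% and 19.9% without thinning. Of 40 shares of cells with a marker or a pair, 33 moved; these settings change both the UMIs per cell and the cells kept, and the parts were not told apart.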

Other observations

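No test was chosen for the observations below after their result was seen, and no difference in them was tested. Within the WT tumor, the epidermal proteases and barrier genes were found in a small part of the Lumino-Basal class. Klk6 stood in the class at 1400 CPM against 13.9 CPM in Mature Luminal and 8.96 CPM in Luminal Progenitor 1 cells, Asprv1 at 1878 against 48.8 and 49.4 CPM, and Krt79 at 467 against 51.0 and 18.4 CPM. These genes led cluster 11, which held 134 of the 1198 cells of the class, where they stood at 19978, 24402 and 6004 CPM. In the 1028 cells of the class in cluster 7 they stood at 29.8, 214 and 56.1 CPM. Krt14 stood at 948 CPM in the class as a whole, and at 537 CPM in its cells of cluster 7, below the 2972 CPM of Basal cells in WT hyperplasia. In cluster 11 Krt14 was at 6591 CPM, above that level. Krt8 was at 194 CPM in cluster 11, against 2151 CPM in the class's cells of cluster 7. Fgb, which encodes a chain of fibrinogen, was a Mature Luminal gene in both tumors, at 1895 CPM in WT and 1356 CPM in PKA. The uroplakin gene Upk3a stood at 1753 CPM in the same class in WT tumor. In WT hyperplasia it had 1 UMI in all cells, against 8666 UMIs in WT tumor (11.90, 9.42 to 17.20).

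The EMT-like class carried little of the genes that define it. Vim stood at 10.6 CPM in WT and 25.8 CPM in PKA cells of the class, and Trim29 and Cldn6 had no UMI in either. Sox4 was at 244 CPM in the class in WT tumor and at 1308 CPM in Lumino-Basal cells of that tumor. The secretoglobin genes Scgb1b27 and Scgb2b27 and the carbonic anhydrase gene Car6 were among the 10 leading genes of the EMT-like class in WT tumor and of the Luminal Progenitor 2 class in both hyperplasia libraries. In PKA tumor, Scgb1b27 and Scgb2b27 were among those of Luminal Progenitor 1, and none of the 3 genes was among those of the EMT-like class. In hyperplasia, Mki67, a gene of cycling cells, was found in Luminal Progenitor 2 in 3.04% (1.67 to 5.04) of WT cells and 6.88% (19 of 276) of PKA cells, against 0.526% (0.263 to 0.940) and 0.284% (0.104 to 0.618) in Luminal Progenitor 1. Of the 25 WT cells with Mki67, 14 were Luminal Progenitor 2 and 11 Luminal Progenitor 1 cells. Mature Luminal cells gave a background of 0 of 88 WT cells and 0 of 174 PKA cells, which allows up to 3.41% and 1.72%, and Basal cells stood at 1.82% (0.221 to 6.41) in PKA. In Luminal Progenitor 2, G2/M genes had a median of 0.74 with PKA and S phase genes 0.27, whereas in Luminal Progenitor 1 they stood at -0.77 and -0.63. The median fraction of mitochondrial UMIs was 4.13% in WT and 4.40% in PKA cells of Luminal Progenitor 2, and 1.69% and 1.61% in Luminal Progenitor 1.

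Other lists stayed near random lists for PKA against WT. In hyperplasia and tumor, immediate early genes stood at 0.08 (percentile 93.3) and 0.05 (90.9), pan-luminal genes at 0.02 (66.3) and -0.19 (33.8), and epithelial adhesion genes at 0.07 (85.6) and -0.09 (56.9). Lipid genes stood at -0.03 (34.9) and -0.20 (20.4), hypoxia genes at 0.02 (59.5) and -0.04 (66.1), and Notch genes at 0.14 (89.6) and -0.23 (18.1). Unfolded protein response genes stood at -0.12 (4.70) and -0.25 (15.3), and mitochondrially encoded genes at 0.02 (66.4) and 0.19 (88.5) with lower sums. Matrix genes stood at -0.04 (30.4) in hyperplasia, mesenchymal genes at -0.22 (2.78), and stem cell and Wnt genes at 0.15 (95.6). In tumor, milk protein genes stood at 0.08 (89.1), the EMT-like genes at -0.28 (18.1) and nuclear oxidative phosphorylation genes at -0.01 (83.5).

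Between the stages, the remaining lists were given for WT and PKA in that order. PKA pathway genes stood at 0.01 and 0.16, S phase genes at 0.47 (70.5) and 0.47 (69.8), and G2/M genes at 0.03 (13.7) and -0.47 (0.19). Interferon response genes stood at -0.19 (6.79) and 0.12 (76.6), antigen presentation genes at 0.19 and 0.26, and Notch genes at 0.87 (95.1) and 1.11 (98.7). Stem cell and Wnt genes stood at 0.71 (94.1) and 0.01 (29.1), hypoxia genes at 0.55 (92.4) and 0.10 (55.7), and mitochondrially encoded genes at -0.72 (0.13) and -0.33 (4.52). Adhesion genes stood at 0.33 (80.0) and -0.24 (18.7), lipid genes at -0.01 and -0.25, unfolded protein response genes at 0.28 (78.9) and 0.16 (82.7), and oxidative phosphorylation genes at -0.12 (20.7) and -0.16 (38.9). The ribosomal protein list had medians of 0.50 (94.0) and 1.32 (100), but their summed CPM was lower in tumors, at 47217 against 93463 in WT and 51935 against 87792 in PKA, and the 85 coding genes alone had medians of -0.75 and -0.58.

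Rps3a1, which encodes a ribosomal protein, stood at 405, 786, 857 and 730 CPM in WT hyperplasia, PKA hyperplasia, WT tumor and PKA tumor, and its processed pseudogene Rps3a3 at 1508, 2.35, 6.61 and 7.64 CPM. The gene and its pseudogene thus went opposite ways between WT and PKA hyperplasia, and whether reads were counted alike in these libraries is not known. Pfn1 stood at 1992, 1929, 39.5 and 35.3 CPM. Markers found in any leukocyte summed to 3.70, 3.57, 3.06 and 2.33 CPM in the same order, macrophage markers to 39.5, 19.7, 27.3 and 16.5 CPM, and endothelial markers to 17.9, 13.9, 10.1 and 4.77 CPM. Other sums came mostly from 1 or 2 genes and are no measure of a cell type. S100a8 gave all 3538 UMIs of the neutrophil markers in WT hyperplasia, where S100a9 had none, and the sums were 328, 485, 27.8 and 296 CPM. Sdc1 gave 4190 of the 4201 UMIs of the plasma cell markers in WT tumor (sums of 78.6, 83.0, 171 and 119 CPM). Mbp gave 734 of the 765 UMIs of the Schwann cell markers in WT hyperplasia (70.8, 68.3, 23.4 and 21.5 CPM). Trbc2 gave 265 of the 281 UMIs of the T cell markers in WT tumor (10.9, 18.9, 11.5 and 2.09 CPM). Notch3 and Mcam gave 787 and 351 of the 1149 UMIs of the pericyte markers in WT tumor (53.8, 60.4, 46.9 and 68.3 CPM).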
